A study of Mus musculus with 8 samples.

How the data were processed

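RNA sequencing measured gene expression in mouse embryonic stem (ES) cells of 2 clonal lines. Clone 6 carries a transgene for Ctcfl that doxycycline switches on, and clone 7 carries no transgene. Ctcfl, also called BORIS, is the germline paralog of the insulator protein Ctcf. Per the labels' protocols, cells kept on mouse embryonic fibroblast feeders were moved to dishes without feeders for 48 h, with 2 µg/ml doxycycline or none, and total RNA was purified, treated with DNase and sequenced as 75 bp single-end reads. The 8 libraries form 4 groups of 2, and each of 2 experiments gave 1 library per group. The labels call these biological replicates and say no more on how far the cultures were separate.

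The authors deposited 1 table with the columns of a Cuffdiff gene table, which holds 23284 gene entries in each of 6 pairwise comparisons of the groups, 139704 lines in all. TopHat2 2.0.8, Cufflinks 2.1.1 (the package that includes Cuffdiff) and genome build mm10 are listed per the submitters' processing notes. The part each tool played, the gene annotation, the strand setting and the library normalization mode are not given in the sources used here. The authors deposited expression as FPKM, fragments per kilobase of transcript scaled to the mapped fragments, with 1 FPKM value per gene and group that combines both experiments. No value per library was used, so the depth of each library is unknown, group values carry no SD, and no library could be left out or paired with another. Per the labels, samples were joined by the experiment tag in their titles, which the deposited group values do not carry. The deposited log2 fold change is the log2 ratio of the group FPKM values with no pseudocount. The deposited test statistic is a score with no fixed range. The deposited p-value has a smallest value of 5e-05, which 481 tests share, so those tests cannot be ranked among themselves.

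The deposited q-value was checked against Benjamini-Hochberg adjustment of the 78127 tests of all 6 comparisons at once, and the largest difference was 5.21e-07. A gene's q-value in 1 comparison therefore depends on how many genes differed in the others, and its smallest value is 0.00812. Some deposited cells were damaged in a spreadsheet. These were 4221 fold change cells and 127 test statistic cells with an error text, and 25 gene names that had become dates. In all of these 4221 fold change cells the second group was at 0. Several gene names stand in 84 gene entries, which were kept as deposited. A further 3634 fold change cells were infinite because a group was at 0. In 12 lines, of 4 genes (Rpl34 with Rpl34-ps1, Snrpn, Snurf and G3bp2), the deposited fold change was not the ratio of the deposited values within a tolerance of 0.01 on the log2 scale, and these genes were left out of the test of the difference between responses. An FPKM of exactly 0 can be a failed estimate, so such a gene is described as listed at 0 and given no fold. FPKM values of very short genes divide by a very short length and are uncertain, and genes that share reads with a near-identical copy or overlap another gene are uncertain too.

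Genes were called changed where the authors' status says that a test was made and the deposited q-value was under 0.05. Fold changes are given as doxycycline over no doxycycline and as transgenic over non-transgenic line, from the deposited FPKM values. The difference between the doxycycline responses of the lines was tested per gene with a two-sided normal test. It divided the difference of the deposited log2 fold changes by the root of their summed squared standard errors, each taken as the log2 fold change over the test statistic, with Benjamini-Hochberg adjustment over 12634 genes. In data simulated for this test on 12634 genes, of which 200 were changed, 6 of 100 genes with a true difference of 1 on the log2 scale and 56 of 100 with a difference of 2 were called, as were 4 of 12434 unchanged genes. The simulated errors were normal, with the same standard errors that the test divides by, so the simulation does not check those standard errors. In the deposited data 58 of 12634 p-values of this normal test were under 0.05 (0.459%), so the simulated shares may not carry over.

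The 22 gene lists cover Ctcf paralogs and cohesin, germline and cancer-testis genes, TGF-beta family signalling, imprinted genes, the pluripotency network, primed epiblast and early ectoderm, mesoderm and primitive streak, endoderm, trophoblast, embryonic fibroblast (feeder) markers, 2-cell-like genes, DNA methylation and histone methylation factors, Hox genes, p53 targets and apoptosis, ATF4 and the unfolded protein response, mitochondrial DNA-encoded genes, glycolysis and hypoxia, cholesterol synthesis, cell cycle, ribosomal proteins, X-inactivation and Y-linked genes, and interferon response. For each list, members called higher, lower or not were counted, also with p adjusted over the list alone. The median log2 fold change on the log2(FPKM + 1) scale, over members at 1 FPKM or more in either group, was placed among 10000 random lists of the same size matched in 10 classes of mean expression, which permutes genes and not libraries. This gave a two-sided p whose smallest possible value is 0.0002, adjusted by Benjamini-Hochberg over the lists of a comparison. The pseudocount understates the change of genes with low values. Genes are not replicates and members of a list are co-regulated, so these p-values describe the deposited group values and not the conditions at large. In a simulation, 5 of 100 unchanged lists of 30 genes had p under 0.05, as did 20 of 20 shifted lists. The unchanged lists were random draws of genes, as in the test itself, so they do not show how it treats co-regulated genes. The shift given to every member was larger than each list median found for doxycycline with the settings above. Smaller shifts and shorter lists were not simulated. Where at least 50 genes were called in a direction, Fisher's exact test (two-sided) compared list members among the called genes with all genes tested in that comparison. Medians per chromosome were tested in the same way as list medians. Correlations of fold changes were taken across genes.

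Ctcfl is always named. In each comparison the named genes are all called genes where there were 30 or fewer, and otherwise the 12 with the largest positive and the 12 with the largest negative fold change among called genes at 5 FPKM or more in the higher group and above 0 in both, without predicted genes, microRNAs and snoRNAs. For each list they are up to 4 called members with the largest test statistics or, with none called, up to 2 with the highest mean. For the difference between responses they are up to 5 in each direction by smallest adjusted p. Some genes that this rule names are not reported here. The tests, the lists, this naming rule and the settings to be varied were fixed before the data were examined. Stra8, Ctcf, Ddit4, Hist1h3c and the genes said below to be chosen after their values were seen stand outside the rule; Ddit4 was taken for the smallest p of its comparison. These settings changed the q threshold, adjusted p within a comparison, required 1 FPKM or a log2 fold change of at least 1, took the standard error from p, and changed the pseudocount, the expression minimum and the enrichment background. A bound on p set by the non-transgenic comparison, and a test of the difference between the lines in the response of each list, were added after seeing the data.

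Coordinates are those of the deposited table, in mm10 and counted from 1. Strand and gene type come from GENCODE M21, where 20836 of the 23284 names and 142 of the 146 named genes were found. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.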

Results

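Gene expression was compared between a mouse ES cell line with an inducible Ctcfl transgene (clone 6, the transgenic line) and a line without it (clone 7, the non-transgenic line), each grown for 48 h with 2 µg/ml doxycycline or without it. Each of the 4 groups was made of 2 libraries, for which the authors deposited 1 FPKM value per gene, so every level below is the authors' group value and carries no SD. Library depth is unknown. The FPKM values summed to 729893 and 737443 in the transgenic line with and without doxycycline and to 721623 and 717813 in the non-transgenic line. Between 12033 and 12092 genes reached 1 FPKM in a group, and between 5220 and 5486 were listed at 0.

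The first question was which genes change with doxycycline, the inducer of the transgene, in the transgenic line. Krt8 and Krt18, the keratins of simple epithelia, rose from 112 to 184 FPKM and from 96.3 to 167 FPKM in the transgenic line. Prss50, a serine protease of the testis, rose from 3.83 to 12.2 FPKM. Rec8, the meiotic subunit of cohesin, rose from 5.74 to 14.1 FPKM. The transcriptional coactivator Cited1 rose from 3.92 to 13.5 FPKM, while Id2, an inhibitor of basic helix-loop-helix factors, fell from 39.8 to 22.8 FPKM. In the authors' deposited table, out of 13003 tested genes, 14 were called, 12 higher and 2 lower with doxycycline. The submitters also state 14, and since the calls are their own deposited ones, this is no separate check.

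Ctcfl itself (chromosome 2, 173093609 to 173119525, minus strand, protein coding) stood at 0.995 FPKM with doxycycline and 0.403 FPKM without it in the transgenic line, against 0.498 and 0.513 FPKM in the non-transgenic line. The authors' deposited table gives a 2.47-fold difference in the transgenic line (log2 1.30, p = 0.0062, q = 0.296), which did not pass the threshold. Which part of Ctcfl the transgene holds is not given in the sources used here, so how much of its transcript this value counts is unknown. Its ubiquitous paralog Ctcf was at 50.5 and 54.0 FPKM in the same groups. Stra8, a gene of meiotic entry chosen after its values were seen, was at 2.71 FPKM with doxycycline and 0.221 FPKM without it, 12.3-fold in the authors' deposited table (p = 0.00095, q = 0.0809).

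Of the other called genes, Dsp, which encodes the desmosomal protein desmoplakin, rose from 9.27 to 17.1 FPKM. Cldn4, a tight junction claudin, rose from 61.0 to 98.4 FPKM, and Cdh3, which encodes P-cadherin, from 14.1 to 25.2 FPKM. The cytokine ligand Tgfb1 rose from 12.7 to 23.6 FPKM and the receptor-associated kinase Jak2 from 2.53 to 5.30 FPKM. Prex2, an exchange factor for Rac, fell from 7.02 to 3.28 FPKM. The uncharacterized gene 1700019B21Rik (chromosome X, 62510539 to 62527011) was at 0.660 FPKM with doxycycline and listed at 0 without it. Folds of the genes that rose ran from 1.61 for Cldn4 to 3.44 for Cited1 in the authors' deposited table, with 3.18 for Prss50, 2.46 for Rec8, 1.65 for Krt8 and 1.73 for Krt18. Id2 and Prex2 had log2 changes of -0.81 and -1.10 in the authors' deposited table. Krt8 (101996711 to 102004342) and Krt18 (102028216 to 102032026) are neighbours on chromosome 15. Prss50 lies on chromosome 9 (110857967 to 110864628) and Rec8 on chromosome 14 (55618166 to 55625395).

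In the authors' deposited table, of the 14 genes 7 (Dsp, Jak2, Krt18, Prss50, Rec8, Prex2 and 1700019B21Rik) had the smallest possible q of 0.00812, and q reached 0.04995 for Cldn4. Adjusting the p-values of the authors' deposited table within this comparison alone left 0 genes under 0.05, with a smallest adjusted p of 0.0929 and 140 genes at an unadjusted p under 0.05.

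**Figure D1:**
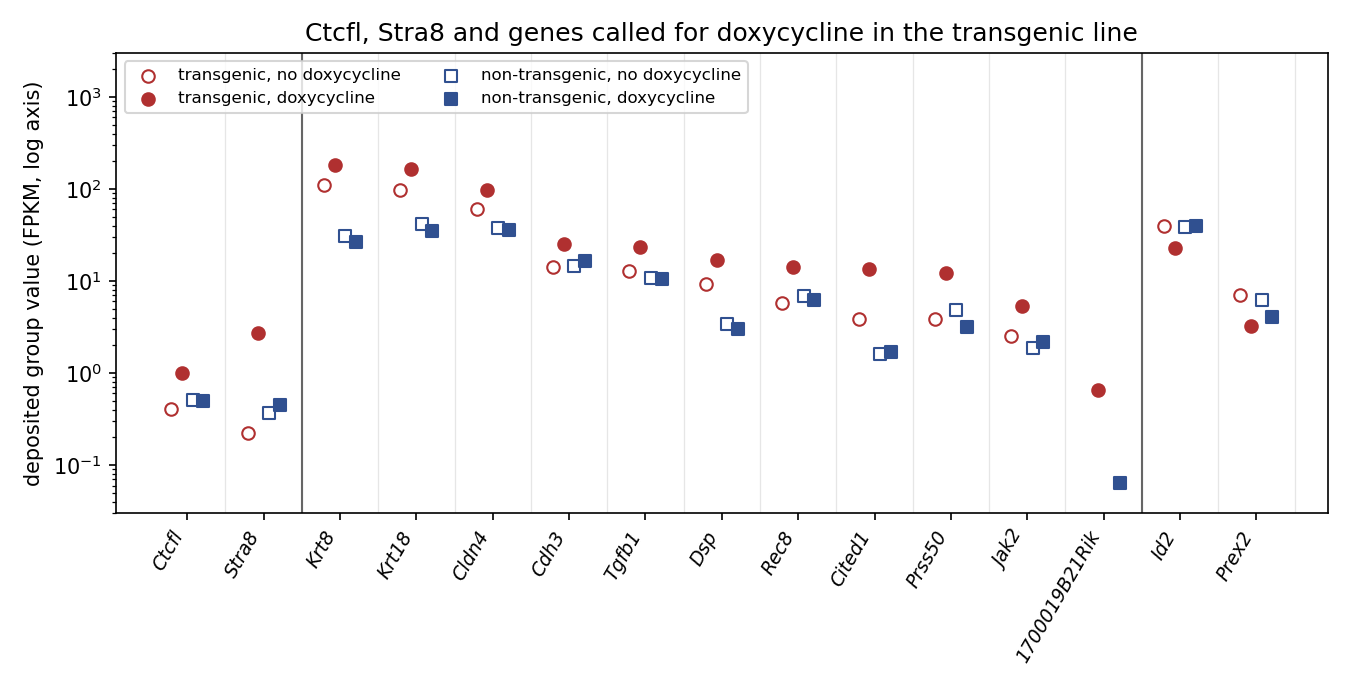
Deposited group values (FPKM, log axis) of Ctcfl, Stra8 and 13 of the 14 genes called for doxycycline in the transgenic line, with circles for the transgenic and squares for the non-transgenic line, filled with doxycycline and open without. The 11 genes between the vertical lines rose and the 2 at the right fell in the transgenic line, and values listed at 0 are not drawn.

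By gene list, the trophoblast genes had a median of 0.28 on the log2 scale with doxycycline in the transgenic line (adjusted permutation p = 0.0010), and of 0.10 with no expression minimum (adjusted permutation p = 0.0175). Of its 12 tested members 2 (Krt8 and Krt18) were called higher and 10 were not called, and 2 were called when adjusted over the list alone. The pluripotency network had a median of 0.15 (adjusted permutation p = 0.0010), with 22 of its 32 members above 0, 0 called by the deposited Cuffdiff-type test and 0 adjusted over the list alone. Its most abundant members, the oocyte and ES cell gene Dppa5a and the core factor Pou5f1, were at 1553 and 1269 FPKM and at 1011 and 1116 FPKM with and without doxycycline. Primed epiblast and early ectoderm genes had a median of -0.21 (adjusted permutation p = 0.0010), with 15 of 16 members below 0. The 1 member called of 17 tested, also when adjusted over the list alone, was Krt18, a keratin gene, which rose. Glycolysis and hypoxia genes had a median of -0.19 (adjusted permutation p = 0.0010), with 22 of 26 members below 0 and 0 called, also over the list alone. Gapdh was at 3039 and 3205 FPKM with and without doxycycline and Pkm2, which encodes pyruvate kinase, at 2233 and 2406 FPKM. Cholesterol synthesis genes had a median of -0.09 (adjusted permutation p = 0.0016; 20 of 24 below 0) and p53 targets and apoptosis genes a median of -0.08 (adjusted permutation p = 0.0107; 19 of 23 below 0), each with 0 called, also over the list alone. The p53 list did not pass at 5 FPKM or more, where its median was -0.04 (adjusted permutation p = 0.338). These p-values before adjustment reached 0.0002 at 4 lists, the smallest that the random lists can give.

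Mesoderm and primitive streak genes had a median of 0.14 (adjusted permutation p = 0.0366) over 13 members, with 0 called and 1, the primitive streak factor T, when adjusted over the list alone; T was at 36.3 and 22.4 FPKM. That direction did not hold at 5 FPKM or more, where the median was -0.01, or with no expression minimum, where it was -0.02, and the list did not pass with a pseudocount of 0.1 (0.16, adjusted permutation p = 0.0675). The germline and cancer-testis list had 1 of 28 tested members called, Prss50, and 2 when adjusted over the list alone, Prss50 and Stra8, with a median of 0.07 (adjusted permutation p = 0.143). Rec8 was the 1 called member of 17 tested Ctcf paralog and cohesin genes, also over the list alone, and the list median was 0.03 (adjusted permutation p = 0.515). The cohesin subunits Rad21 and Smc3 were at 80.9 and 81.9 FPKM and at 57.1 and 56.0 FPKM. TGF-beta family signalling had 1 of 50 tested members higher, Tgfb1, and 1 lower, Id2, the same counts when adjusted over the list alone, and a median of -0.01 (adjusted permutation p = 0.645).

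No member was called, over all genes or over the list alone, in the remaining lists of this comparison. Their medians were 0.08 for endoderm (adjusted permutation p = 0.0700), -0.07 for interferon response (0.143), -0.05 for X-inactivation and Y-linked genes (0.528), -0.03 for ATF4 and the unfolded protein response (0.515). They were -0.02 for cell cycle (0.651) and for DNA methylation and histone methylation factors (0.645), -0.01 for imprinted genes (0.782) and ribosomal proteins (0.618), and -0.0009 for feeder markers (0.870). Endoderm genes passed at 5 FPKM or more (0.14, adjusted permutation p = 0.0133). Of the 2-cell-like genes 1 reached 1 FPKM (Zfp1, 16.1 and 17.9 FPKM; -0.15, adjusted permutation p = 0.265). Of 39 Hox genes 4 were tested, none reached 1 FPKM and none was called in any comparison, and 0 of 15 mitochondrial DNA-encoded genes were in the table.

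The second comparison asked what doxycycline does in cells without the transgene. In the non-transgenic line the keratins Krt8 and Krt18 were at 26.8 and 35.0 FPKM with doxycycline and 30.8 and 41.8 FPKM without it. Prss50 was at 3.21 and 4.82 FPKM, Rec8 at 6.16 and 6.93 FPKM, Cited1 at 1.69 and 1.61 FPKM and Tgfb1 at 10.5 and 10.8 FPKM. Id2 was at 40.0 and 39.0 FPKM and Prex2 at 4.10 and 6.21 FPKM. The Cuffdiff-type test of the authors' deposited table called 0 of 12908 tested genes, with 14 genes at an unadjusted p under 0.05 and a smallest q of 0.444. The smallest p of the authors' deposited table in this comparison was 0.01175, at Ddit4, an inhibitor of growth signalling that hypoxia induces, which was at 43.9 and 65.85 FPKM. Prex2 also had a p of 0.01485 in the authors' deposited table, with a log2 change of -0.60.

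Gene lists nevertheless moved in this line. The pluripotency network had a median of 0.17 (adjusted permutation p = 0.0020), with 31 of 32 members above 0; Dppa5a was at 1431 and 1218 FPKM and Pou5f1 at 1108 and 1080 FPKM. Glycolysis and hypoxia genes had a median of -0.17 (adjusted permutation p = 0.0020), with 22 of 26 below 0; Gapdh was at 2990 and 3213 FPKM and Pkm2 at 2422 and 2641 FPKM. All other list medians had adjusted p of 0.0693 (trophoblast, -0.12) or more, and 0 members of any list were called, also over the list alone. At 5 FPKM or more the interferon list also passed, with a median of -0.18 (adjusted permutation p = 0.020).

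**Figure D2:**
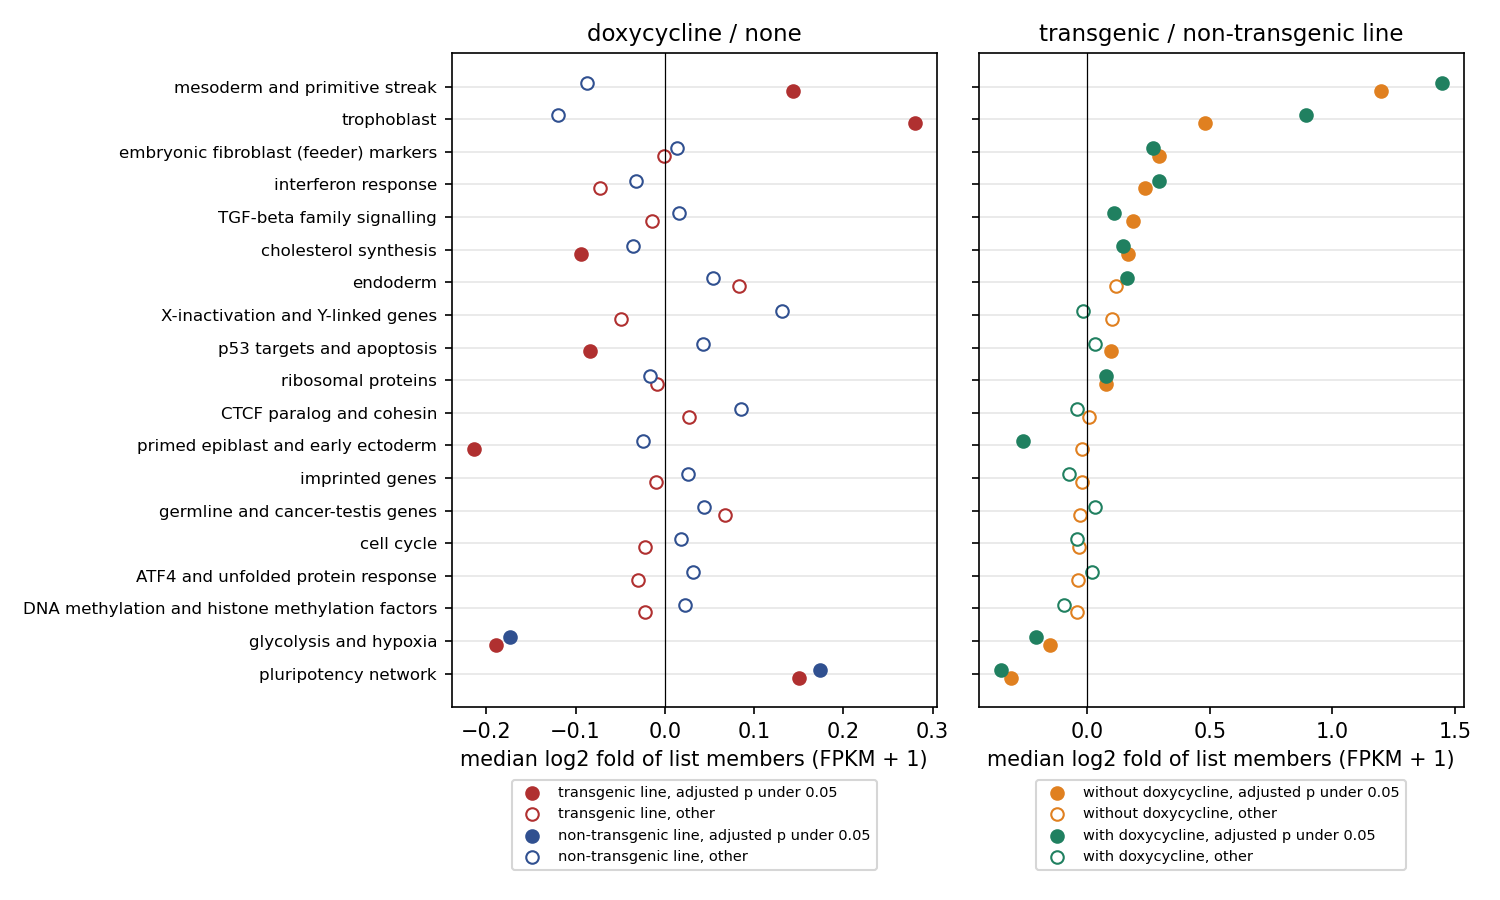
Median log2 fold change (FPKM + 1) of each gene list with at least 5 members at 1 FPKM or more, for doxycycline over none in each line (left) and for the transgenic over the non-transgenic line in each medium (right), with filled points where the adjusted p was under 0.05. The pluripotency network lies at 0.15 and 0.17 and glycolysis and hypoxia at -0.19 and -0.17 for doxycycline in the transgenic and the non-transgenic line.

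Whether a response differs between the lines was tested directly. Each line is a single clone, so a difference between the responses is not assigned to the transgene. By the normal test on the authors' deposited statistics, the response of Prss50 was higher in the transgenic line by 2.26 on the log2 scale (SE 0.53, p = 1.8e-05, adjusted p = 0.0126). This test is an approximation with 2 libraries per group. The log2 change of Prss50 was 1.67 in the transgenic and -0.59 in the non-transgenic line. Of 12634 genes 18 were called, 11 with the response higher and 7 with it lower in the transgenic line, and 15 of the 18 are microRNA or snoRNA genes. Krt18 (difference 1.05, SE 0.30, p = 0.000454, adjusted p = 0.239), Krt8 (0.92, p = 0.00194, adjusted p = 0.817), Rec8 (1.47, p = 0.00279) and Cited1 (1.71, p = 0.00542) were not called from the authors' deposited statistics. The other genes called for doxycycline and tested here were not called either. Their p by this normal test ran from 0.0120 for Dsp to 0.455 for Prex2. Standard errors taken from the deposited p in place of the test statistic left 0 genes called by this normal test, with 26 at an unadjusted p under 0.05, and gave Prss50 a p of 0.000415. Across 12566 genes at 1 FPKM or more in a group, which are not independent replicates, the responses of the lines had a Spearman rho of 0.132 and a Pearson r of -0.04.

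For the lists, each member's response in the transgenic line minus that in the non-transgenic line was taken, in a test added after seeing the data. The median of these differences was -0.24 for primed epiblast and early ectoderm genes (adjusted permutation p = 0.0020 over 20 lists). It was 0.31 for mesoderm and primitive streak genes (adjusted permutation p = 0.0020) and 0.26 for trophoblast genes (adjusted permutation p = 0.0080). A median of differences need not equal the difference of the list medians given above. Only 7 of the 13 mesoderm members reached 1 FPKM in the non-transgenic line, and at 5 FPKM or more that difference did not pass (0.23, adjusted permutation p = 0.120). With a pseudocount of 0.1 the mesoderm and trophoblast differences were 0.50 and 0.42, and at 5 FPKM or more the trophoblast difference was 0.46. The pluripotency and glycolysis lists differed by 0.00 and -0.03 (adjusted permutation p = 0.739 for both).

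**Figure D3:**
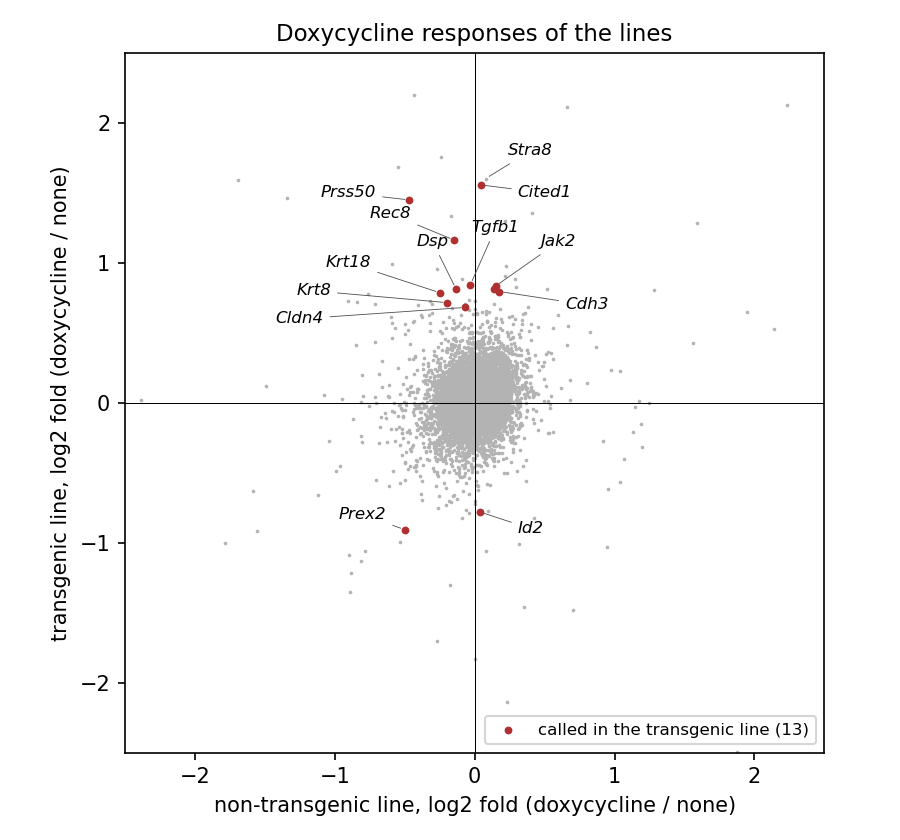
Log2 fold change (FPKM + 1) for doxycycline over none in the transgenic line (vertical axis) against the non-transgenic line (horizontal axis), for 12566 genes at 1 FPKM or more in a group, 106 of them outside the axes. The 13 called genes that reach 1 FPKM are red, and 11 of them lie above and 2 below 0 on the vertical axis.

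The third comparison set the lines against each other without doxycycline. Each line is a single clone, so a difference between the lines is not assigned to the transgene. Genes of the primitive streak were higher in the transgenic line. T was at 22.4 FPKM against 1.67 FPKM, the signal Fgf8 at 61.8 against 7.01 FPKM, the T-box factor Eomes at 18.8 against 2.79 FPKM and the ligand Wnt3 at 7.02 against 1.44 FPKM. Olig1, a transcription factor of the oligodendrocyte lineage, had the largest fold of the named genes, at 54.5 against 0.312 FPKM. Meg3, a noncoding RNA expressed from the maternal allele, was lower, at 66.7 against 217 FPKM, as were the homeobox gene Gbx2 at 6.04 against 25.0 FPKM and Tcf15 at 50.9 against 188 FPKM. The authors' deposited table called 179 of 13047 tested genes, 104 higher and 75 lower in the transgenic line, with 860 at an unadjusted p under 0.05.

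In the authors' deposited table Olig1 differed 174-fold, T 13.4-fold and Fgf8 8.81-fold, each at a q of 0.00812. Other genes higher in the transgenic line were the Wnt-responsive factor Sp5 (24.0 and 2.99 FPKM), the ligand Wnt8a (17.3 and 2.45 FPKM), and the testis cytochrome c gene Cyct (20.1 and 2.25 FPKM). Also higher were the ubiquitin ligase Mid1 (57.4 and 11.4 FPKM), lymphotoxin beta (Ltb, 20.2 and 4.94 FPKM), Ppp4r4 (13.1 and 3.11 FPKM) and the neurofilament gene Nefl (89.0 and 24.3 FPKM). Lower were Rnf165 (1.07 and 5.18 FPKM), Tagln3 (1.59 and 6.27 FPKM), H2-Bl (1.22 and 5.68 FPKM) and Dhrs7 (3.81 and 12.8 FPKM). So were the potassium channel gene Kcnj3 (5.14 and 12.8 FPKM), the kinase gene Hunk (7.06 and 17.1 FPKM), Dlc1 (12.1 and 28.0 FPKM) and the orphan receptor Nr0b1 (10.1 and 28.0 FPKM).

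Mesoderm and primitive streak genes had a median of 1.20 (adjusted permutation p = 0.00057), with 5 of 13 tested members called higher (8 when adjusted over the list alone) and 8 not called. The called members were more than chance by Fisher's exact test (adjusted p = 1.57e-06). Trophoblast genes stood at 0.48 (0.00057), with 3 of 12 higher, also over the list alone (Fisher's adjusted p = 0.00126). These were Krt8 at 112 against 30.8 FPKM, Krt18 at 96.3 against 41.8 FPKM and Eomes, which the mesoderm list also holds. Feeder markers had a median of 0.29 (0.00057) with 31 of 34 members above 0, but 1 called, the smooth muscle gene Tagln (188 against 101 FPKM), and 5 over the list alone. TGF-beta family signalling had a median of 0.19 (0.00057) and 3 of 50 higher, also over the list alone. Among these were Nodal (56.7 against 24.0 FPKM) and the activin antagonist Fst (20.2 against 7.09 FPKM). Cholesterol synthesis had a median of 0.17 (0.00057) with 1 called, and interferon response 0.24 (0.0035) with 0 called, each with the same count over the list alone. Ribosomal proteins had a median of 0.08 (0.0284), with 0 called and 33 of 37 above 0. In the TGF-beta list 3 members were called higher against 0.399 expected, which did not pass Fisher's exact test after adjustment (adjusted p = 0.0647). Only the mesoderm and trophoblast lists passed this test among the higher genes, and only the pluripotency and imprinted lists among the lower ones. The sizes of the mesoderm and trophoblast medians depend on which genes are kept, being 0.37 and 0.21 with no expression minimum and 2.68 and 1.18 at 5 FPKM or more. With no expression minimum the interferon list did not pass (0.07, adjusted permutation p = 0.0916).

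The pluripotency network was lower in the transgenic line, with a median of -0.31 (adjusted permutation p = 0.00057). Of its 32 members 5 were called lower and 2 higher (11 and 2 over the list alone), and 25 were not called. The lower ones exceeded chance by Fisher's exact test (adjusted p = 2.15e-05). Nr0b1 and Rex2 (16.2 against 33.8 FPKM) were lower, while Zfp42, a marker of undifferentiated ES cells, was higher at 58.8 against 18.9 FPKM, as was the core factor Nanog at 97.6 against 57.9 FPKM. Glycolysis and hypoxia genes had a median of -0.15 (0.00057), with 2 of 27 called lower, also over the list alone: the oxygen-sensing hydroxylase gene Egln3 (10.4 against 20.3 FPKM) and Bnip3 (58.1 against 94.5 FPKM). Against 0.155 expected, this did not pass Fisher's exact test after adjustment (adjusted p = 0.0656). Among 44 tested imprinted genes 4 were lower and 1 higher (5 and 1 over the list alone), the lower ones more than chance (Fisher's adjusted p = 0.00126). The list median of -0.02 did not pass (0.655). Meg3 (chromosome 12, 109540996 to 109571729), Mirg (109734981 to 109749457; 8.74 against 34.0 FPKM) and Rian (109603945 to 109661711; 48.3 against 115 FPKM) are neighbours and so not independent. Peg3, expressed from the paternal allele, was higher at 29.2 against 8.72 FPKM.

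Among the other lists, p53 targets and apoptosis genes had a median of 0.10 (adjusted permutation p = 0.0147), with the cell cycle inhibitor Cdkn1a higher (63.7 against 35.4 FPKM), the p53-induced killer gene Pmaip1 lower and 3 higher and 1 lower over the list alone. Primed epiblast genes had 2 of 18 higher (Wnt8a and Krt18) and 1 lower (Foxd3, 23.2 against 41.4 FPKM), 4 and 3 over the list alone, and a median of -0.02 (0.748). The germline list had 1 of 27 called, also over the list alone, the synaptonemal gene Sycp1 (3.73 against 0.727 FPKM). The DNA methylation list had 1 of 27 called, the methyltransferase cofactor Dnmt3l (120 against 206 FPKM; 3 over the list alone), and endoderm 1 of 17, Lama1 (1.54 against 3.48 FPKM; 3 higher and 1 lower over the list alone). Cell cycle had 1 of 32, Cdkn1a, and the X-inactivation and Y-linked list 1 of 8, Kdm5d (1.40 against 0.299 FPKM), while the Y-linked Eif2s3y was at 43.0 against 38.4 FPKM. Except for the p53 list, the medians of these lists did not pass, nor did those of the cohesin, 2-cell-like and ATF4 lists. The adjusted permutation p of the medians that did not pass lay between 0.0604 (endoderm) and 0.748 (2-cell-like genes). At 5 FPKM or more the germline and endoderm lists did pass, with medians of -0.22 and 0.32 (adjusted permutation p = 0.0022 for both). Endoderm also passed with a pseudocount of 0.1 (0.20, adjusted permutation p = 0.0140), and the X-inactivation and Y-linked list with no expression minimum (0.12, adjusted permutation p = 0.0315).

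The fourth comparison set the lines against each other with doxycycline in the medium of both. T was at 36.3 FPKM in the transgenic and 2.02 FPKM in the non-transgenic line, Olig1 at 49.1 against 0.293 FPKM, Krt8 at 184 against 26.8 FPKM and Cited1 at 13.5 against 1.69 FPKM, all higher. The retinoic acid hydroxylase gene Cyp26a1 was higher at 5.27 against 0.697 FPKM. Meg3 (66.2 against 221 FPKM), Gbx2 (7.77 against 37.2 FPKM) and Insm1 (1.86 against 6.00 FPKM) were lower. Fgf8 (55.1 and 5.81 FPKM), Sp5 (34.4 and 3.34 FPKM), Wnt3 (7.87 and 1.07 FPKM), Cyct (21.5 and 2.31 FPKM), Ltb (23.3 and 3.85 FPKM) and Dsp (17.1 and 2.99 FPKM) were higher too. Tcf15 (60.5 and 199 FPKM), Nr0b1 (15.1 and 41.8 FPKM), Dhrs7 (3.58 and 12.98 FPKM), Rnf165 (1.09 and 5.70 FPKM) and Tagln3 (1.01 and 6.07 FPKM) were lower. So were the exocyst-like gene Exoc3l (4.61 and 14.6 FPKM), the junctional adhesion gene Jam2 (1.85 and 5.20 FPKM) and Kcnj3 (3.43 and 11.7 FPKM). The authors' deposited table called 199 of 13064 tested genes, 112 higher and 87 lower, with 1032 at an unadjusted p under 0.05. In the authors' deposited table Sp5 differed 10.3-fold, Krt8 6.87-fold, Cited1 7.97-fold and Olig1 168-fold.

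Mesoderm and primitive streak genes had a median of 1.45 (adjusted permutation p = 0.00067), with 5 of 14 called higher and 10 higher and 1 lower over the list alone (Fisher's adjusted p = 1.75e-06). Trophoblast genes had a median of 0.89 (0.00067) and 3 of 12 higher, 7 over the list alone (Fisher's adjusted p = 0.00140). TGF-beta family signalling had a median of 0.11 (0.0031) and 5 of 50 higher, 8 higher and 2 lower over the list alone (Fisher's adjusted p = 0.000968), among them Tgfb1 (23.6 against 10.5 FPKM) and the Nodal antagonist Lefty1 (324 against 185 FPKM). Feeder markers stood at 0.27 (0.00067), with 26 of 34 above 0 and 2 called, Acta2 (131 against 68.1 FPKM) and Tagln (219 against 105.5 FPKM), 7 over the list alone. Endoderm genes had a median of 0.16 (0.0204), with Krt19 higher (38.5 against 12.4 FPKM) and Lama1 lower, 2 and 1 over the list alone. Interferon response (0.29, 0.0030), cholesterol synthesis (0.15, 0.0023) and ribosomal proteins (0.07, 0.0225) were also above 0, with 0, 1 and 0 members called, and the same counts over the list alone. The mesoderm and trophoblast medians were 0.62 and 0.34 with no expression minimum, 2.59 and 1.63 at 5 FPKM or more, and 2.29 and 1.49 with a pseudocount of 0.1. With no expression minimum the interferon and endoderm lists did not pass (0.04 and 0.06, adjusted permutation p = 0.319 and 0.105). Endoderm genes stood at 0.30 at 5 FPKM or more (adjusted permutation p = 0.0089). Ribosomal proteins did not pass at 5 FPKM or more (0.07, adjusted permutation p = 0.0516).

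The pluripotency network had a median of -0.35 (adjusted permutation p = 0.00067), with 6 lower and 2 higher of 32, 11 and 2 over the list alone (Fisher's adjusted p = 1.75e-06). Mycn was among the lower ones, at 116 against 207 FPKM. Primed epiblast genes stood at -0.26 (0.00067; -0.17 with no expression minimum), with 3 lower and 2 higher of 18, 5 and 3 over the list alone (Fisher's adjusted p = 0.00159). The POU factor Pou3f1 was lower at 54.0 against 95.7 FPKM, while Krt18 and Wnt8a were higher (Fisher's adjusted p = 0.0560 for higher members). Glycolysis and hypoxia genes stood at -0.21 (0.00067), with Bnip3 and Egln3 called lower, also over the list alone. These 2 genes, against 0.173 expected, did not pass Fisher's exact test after adjustment (adjusted p = 0.0628). Imprinted genes had 4 lower and 1 higher of 44, 5 and 1 over the list alone (Fisher's adjusted p = 0.00159). DNA methylation factors had 3 lower of 27, 4 over the list alone (Fisher's adjusted p = 0.00467), namely Dnmt3l, Tet1 (14.7 against 25.1 FPKM) and Tet2 (2.36 against 4.31 FPKM), the last pair being enzymes that oxidise methylcytosine. The germline list had Prss50 (12.2 against 3.21 FPKM) and Sycp1 higher of 27, and 3 higher and 1 lower over the list alone. Cdkn1a was higher and Pmaip1 lower in the p53 list, Cdkn1a was also the called member of the cell cycle list and Kdm5d that of the X and Y list, with the same counts over the list alone. Rec8 was called over the cohesin list alone. The medians of these 3 lists, and of the p53, cell cycle, cohesin, ATF4, 2-cell-like and X and Y lists, did not pass (adjusted p from 0.131 to 0.938).

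The difference between the lines was largely shared by the media, whose comparisons use no library in common. Of 12853 genes tested in both, 79 were called higher and 60 lower in the transgenic line in both media, where independent lists would share 0.906 and 0.502, and 0 were called in opposite directions. The log2 differences in the 2 media had a Spearman rho of 0.657 and a Pearson r of 0.20 across 12566 genes. Comparing transgenic cells with doxycycline against non-transgenic cells without it, the authors' deposited table called 211 of 13060 genes, and for the opposite pairing of media 179 of 13045.

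**Figure D4:**
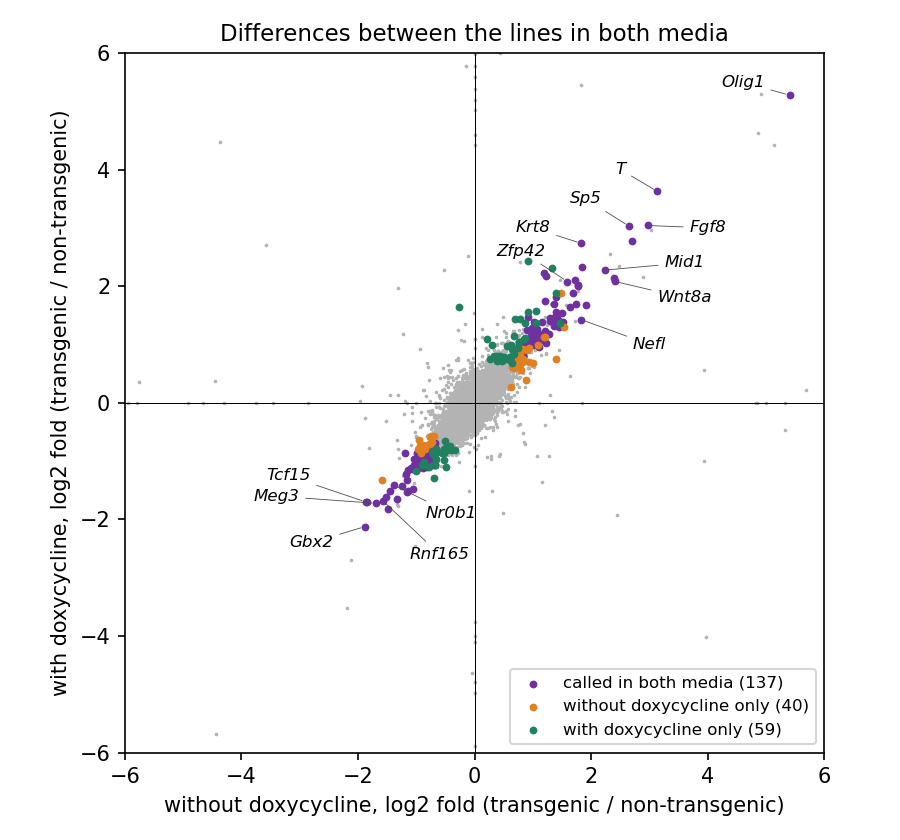
Log2 fold change (FPKM + 1) of the transgenic over the non-transgenic line with doxycycline (vertical axis) against that without it (horizontal axis), for 12566 genes at 1 FPKM or more in a group, 60 of them outside the axes. Purple marks 137 genes called in both media, orange 40 called without and green 59 called with doxycycline, and Olig1 and T lie far above 0 on both axes.

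Medians of the line difference were also taken per chromosome. Relative to all genes, the X chromosome stood at 0.07 without doxycycline (432 genes, adjusted permutation p = 0.0021) and 0.04 with it (430 genes, adjusted permutation p = 0.0260). Without doxycycline chromosome 8 stood at -0.03 (adjusted permutation p = 0.0021). With doxycycline chromosomes 12 and 13 stood at -0.05 and -0.04 and chromosome 17 at 0.04 (adjusted permutation p = 0.0014 for each), and chromosome 15 at 0.03 (adjusted permutation p = 0.0260). Only the X chromosome passed in both media. Chromosome 8 stood at -0.006 with doxycycline (adjusted permutation p = 0.854). Chromosomes 12, 13, 17 and 15 stood at -0.002, -0.007, 0.003 and -0.01 without it (adjusted permutation p from 0.393 to 0.830). The Y chromosome, with 6 genes, had the largest shift but did not pass, at 0.32 without doxycycline (adjusted permutation p = 0.0518) and 0.15 with it (adjusted permutation p = 0.430).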

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

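The per-gene test of the difference between the doxycycline responses was planned; the test of the list differences, and both tests of the explanations for the short RNA genes, were chosen after the results were seen.

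The response to doxycycline differed between the lines at 18 genes by the normal test on the deposited statistics, all values being the transgenic minus the non-transgenic response on the log2 scale. Prss50 differed by 2.26. The noncoding snoRNA host gene Snhg9 differed by 1.17, with a standard error of 0.15 from the statistic but 1.47 from the deposited p. Its log2 change was 0.06 in the transgenic and -1.11 in the non-transgenic line. The histone gene Hist1h3c, named because only 3 of the 18 are not microRNA or snoRNA genes and chosen after its values were seen, differed by 6.20, with standard errors of 1.26 and 2.75. Among the named microRNA genes, Mir20a differed by -4.55, Mir363 by -1.14, Mir692-1 by -0.66, Mir1906-1 by -0.57 and Mir1949 by -0.10, and Mir684-2 by 0.96 and Mir25 by 0.53. The snoRNA genes Snord1b and Snord104 differed by 0.77 and 0.19.

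The pattern is that 15 of the 18 are microRNA or snoRNA genes, although the 61 such genes make up 0.483% of those tested. A candidate explanation is that the deposited test statistic understates the error of these very short genes. The standard error taken from the deposited p was 59.3 times that taken from the statistic in the median of the 15 called. In the median of all genes that are not microRNA or snoRNA genes it was 0.714 times. The 15 were called with the error from the statistic, which favours genes where that error is small. These medians thus do not show how the statistic treats short RNA genes at large. A response of these RNAs that depends on the transgene stays open, since with the standard error from p their smallest p was 0.174. Each line is a single clone, so such a response could not be told apart from a difference between the clones. For Prss50 the errors were close (1.21 times), and its p was 0.000415 with the larger error, past no adjusted threshold.

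The median over list members of the difference between the lines in response was -0.24 for primed epiblast and early ectoderm genes. For trophoblast genes it was 0.26. The mesoderm and primitive streak list gave 0.31, but 7 of its 13 members reached 1 FPKM in the non-transgenic line, where the pseudocount flattens the response of the rest. The mesoderm difference was larger with a pseudocount of 0.1, as given above. At 5 FPKM or more it did not pass (0.23, adjusted permutation p = 0.120), so no difference is drawn from it. The trophoblast list shares Krt18 with the epiblast list and Cdx2, Eomes and Hand1 with the mesoderm list.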

How the results depend on the processing

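Every alternative here was planned except the bound on p and the list differences, which were chosen after the results were seen. No paired analysis was possible because the deposited table holds 1 value per group, without the experiments. Leaving out a replicate and the replicate block were not run for the same reason. Library depth is unknown, so what depth limits could not be measured. For the genes changed by doxycycline in the transgenic line, 14 became 7 at a q threshold of 0.01, 6 with a log2 fold change of at least 1, 0 with p adjusted within the comparison and 0 with 1 FPKM required and p adjusted again, since the adjustment over all comparisons draws on the small p-values between the lines. A p below 0.01175, the smallest of the non-transgenic comparison, took 40 genes, 30 higher and 10 lower. The 0 genes of the non-transgenic line stayed at 0 under the 5 planned settings, with 14 at an unadjusted p under 0.05 in the Cuffdiff-type test. The line difference moved from 179 to 97 genes at a q threshold of 0.01 and to 119 with a log2 fold change of at least 1 without doxycycline, and from 199 to 125 at 0.01 with it, by the stricter limits alone. Genes called in both media went from 139 to 77 at 0.01. The difference between responses went from 18 genes to 0 with the standard error taken from p. In total 25 counts or values that answer a comparison kept within their limits and 10 moved. Among single genes and lists 282 settings gave the same verdict, 27 were weaker, 6 stronger and 2 reversed, both for the mesoderm list with doxycycline in the transgenic line, at -0.0218 with no expression minimum and -0.00918 at 5 FPKM or more; the cause was not tested, and the list has 13 members.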

Other observations

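The tests of low expression, of variation between experiments and of the correlation within lists, and the bound on p in the next paragraph, were chosen after the results were seen; the tests of GC content and transcript length and of a scale factor were set before theirs.

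Of the genes with doxycycline in the transgenic line, 40 had a deposited p below 0.01175, the smallest in the non-transgenic line, and 26 of them were not called by q. The deposited q of these 26 reached 0.427. By its construction the bound leaves no gene of the non-transgenic line below it. The 40 are fewer than evenly spread p-values would put below it, so they are not a list of genes that responded. The genes named here were chosen after their values were seen. Stratifin (Sfn) was at 329 FPKM with doxycycline and 232 FPKM without it, and the cornified envelope gene Sprr2a2 at 2.15 and 0.981 FPKM. The metallothionein genes Mt1 and Mt2 were at 902 and 582 FPKM and at 1359 and 889 FPKM. Zfp42 was at 88.3 and 58.8 FPKM and the E3 ligase gene Rlim at 81.6 and 60.1 FPKM, while the epiblast signal Fgf5 (15.3 and 22.6 FPKM), Fgf15 (8.11 and 13.3 FPKM) and Nefl (61.9 and 89.0 FPKM) were lower with doxycycline. In the non-transgenic line Sfn was at 97.7 and 100.3 FPKM, Mt1 at 944 and 892 FPKM, Zfp42 at 20.1 and 18.9 FPKM and Fgf5 at 12.5 and 12.9 FPKM. The difference between the lines in the response to doxycycline was not called for these genes.

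In the non-transgenic line 14 of 12908 deposited p-values were under 0.05, a share of 0.108% (exact 95% interval 0.0593 to 0.182%, for counting error only, over genes that are not independent), where evenly spread p-values would give 5%. The transgenic line also lay below this, with 140 of 13003 (1.08%, exact 95% interval 0.906 to 1.27%) and a median p of 0.717. Low expression of the tested genes is argued against, since the share in the non-transgenic line was 0.122% at 10 FPKM or more. Variation between the 2 experiments counted as error could give such p-values and stays open: the median p of that line was 0.759, but the experiments cannot be told apart in values given per group. No biological explanation was tested.

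The median of the glycolysis list was lower and that of the pluripotency list higher with doxycycline in both lines, though no member of either was called. Of 26 glycolysis members 20 lay below 0 in both lines, and of 32 pluripotency members 22 lay above 0 in both and 1 below 0 in both. In the transgenic line 10 pluripotency members lay below 0, among them Pou5f1 (1011 and 1116 FPKM with and without doxycycline). The genes that follow moved in the direction of their list in both lines. In the transgenic and then the non-transgenic line, each with doxycycline before without, Pgk1 was at 648 and 859 FPKM and at 825 and 953 FPKM, Ldha at 1260 and 1581 FPKM and at 1462 and 1667 FPKM, Egln3 at 6.78 and 10.4 FPKM and at 14.1 and 20.3 FPKM, Nr0b1 at 15.1 and 10.1 FPKM and at 41.8 and 28.0 FPKM, and Esrrb at 28.6 and 19.7 FPKM and at 43.1 and 32.8 FPKM, all chosen after their values were seen except Egln3 and Nr0b1.

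For this pattern, GC content and transcript length as the whole cause are argued against, since after removing their trend the largest p of the 4 list medians was 0.00020, the smallest that the random lists can give, with medians of -0.18 and 0.15 in the transgenic and -0.18 and 0.17 in the non-transgenic line (25 of 26 and 32 of 32 members had a transcript). A scale factor between libraries shifts all genes alike, so lists that moved in opposite directions already argue against it as the whole cause. The outcome of that test was thus set by the pattern itself. The median of all genes lay at most 0.0212 from 0. A candidate explanation is doxycycline acting on both lines: across the genes of a list the responses of the lines correlated with a Spearman rho of 0.499 for glycolysis and 0.570 for pluripotency, over genes that are not independent. A difference in handling or library batch between the media within each experiment is not labelled and stays open as untested, and no single gene of either list was called.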
